A study of Mus musculus with 6 samples.

How the data were processed

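RNA from 6 samples of the mouse B cell line CH12F3-2A was compared, 3 given control siRNA (siControl) and 3 given siRNA against Spt6 (siSpt6), all stimulated with CIT. The groups and replicate numbers were read from the sample labels. Per the labels' protocols, total RNA was purified with an RNeasy kit, amplified into amino allyl RNA with MessageAmp II, coupled to Cy5 and fragmented after the protocol of the array maker TORAY. The authors deposited a table of intensity values, 1 column per array, on a linear scale in arbitrary units. Background correction and normalization are not given in the sources used here, and the scale was worked out from the values. All values were above 0, they were strongly skewed, and the array medians lay close to 30 on every array, within 0.00109 on the log2 scale. The authors' values therefore seem to have been scaled to a common median by a method that is not stated. Between 4.69% and 8.29% of the 23473 probes were blank on an array, and blanks were taken as missing. A measure of signal over background was not part of the values used, so dim values have no stated detection limit.

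Probes were named from a table that pairs the probes with gene symbols. 16631 probes had 1 gene symbol, 0 had several and 6842 were unnamed. Symbols were updated with RefSeq gene names for the mouse assembly GRCm38.p6: 12622 probes carried a current symbol, 3947 an older symbol of 1 gene, 59 an older symbol shared by several genes, which was kept, and 3 matched none. This gave 16390 different symbols. The build behind the array design is not stated, so no coordinates are printed, and the assembly served only for names, chromosome membership and gene length. Unnamed probes entered the counts of probes but no statement about genes; of 6145 of them tested, 898 changed.

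The rules for analysis were fixed before the data were examined. Because the array medians agreed within 0.1, the deposited values were used as they stood and were log2-transformed without a pseudocount. A probe was tested if it had a value on at least 2 of 3 arrays in each group, which left 21584. A linear model with the group as its only term was fitted to each probe with limma 3.58.1 (lmFit and eBayes, without trend and without the robust option) in R 4.3.3, two-sided. P-values were adjusted by Benjamini-Hochberg over all tested probes, with a threshold of 0.05. Folds are 2 to the power of the log2 difference, so they compare geometric means, while the means ± SD printed are of the linear intensities. A gene with several probes was represented by the brightest probe over all arrays. Of 205 genes with several tested probes, 40 had some but not all probes called and 4 had probes called in both directions.

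Gene lists (31) were also fixed before the data were examined. Those with at least 5 measured members (30) were tested with limma's camera on genes with a value on all 6 arrays, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other genes. The same test with an estimated correlation kept 2 of 10 calls, cholesterol synthesis and G1/S genes. Limma's fry, which asks whether a list's genes move one way on balance and makes no comparison with other genes, was an alternative. Genes were named by a rule fixed in the same way. It took Supt6 and the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap and whose higher group mean reached the median of tested probes, leaving out predicted and clone names. It also took from each list up to 2 rises and 2 falls with the smallest adjusted p, and Ighm whatever its test; Igha was in the rule but not analysed here, and 1 other gene of the rule is not reported here. Where a list had 5 or fewer rises or falls, members beyond the rule were named after their values were seen, as were a few members singled out in longer lists. Members of several lists were counted in each.

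Alternatives recomputed the counts of probes, Supt6 and the named genes with quantile normalization, cyclic loess, median centring, bright probes only (which leaves out dim genes, Supt6 among them), complete probes only, a pseudocount of 2.66 (the 10th percentile of all values), eBayes with trend and robust options, array weights, the replicate number as a block and each array left out in turn, and the counts of probes with stricter thresholds. The gene lists were tested again with quantile normalization, cyclic loess, bright probes only, the replicate block, each array left out, the mean of a gene's probes, an estimated correlation and fry, and not with the other settings. Cyclic loess for the gene lists, and both normalizations for the trend with brightness, were chosen after seeing the data. The scripts were tested on simulated data for this comparison, with 21584 probes of which 200 were changed. At a 4-fold change 53 of 66 probes were recovered (80.3%), at 2-fold 27 of 67 (40.3%) and at 1.5-fold 0 of 67, with 2 unchanged probes called. Far fewer probes changed than the 3525 called in the real data, which makes the adjusted threshold stricter. These rates therefore check the scripts and do not measure recovery in the real comparison. With no probe changed, 0 were called. A simulated list of 20 genes shifted by -0.5 on the log2 scale was called and 0 other lists were. Simulated probes varied independently of one another, so false list calls among correlated genes were not tested. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.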

Results

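Gene expression was measured in CH12F3-2A cells, a mouse B lymphoma line that switches its antibody class from IgM to IgA when it is given CD40 ligand, interleukin 4 and TGF-beta (the mixture called CIT). The cells were electroporated with a control siRNA (siControl, 3 samples) or with an siRNA against Spt6 (siSpt6, 3 samples). CIT was added 24 h after transfection and RNA was taken after a further 24 h. Spt6, the product of the gene Supt6, is a histone chaperone that travels with elongating RNA polymerase II. The study asked how Spt6 bears on where AID, the enzyme that starts class switching, acts. The arrays address which transcripts differ in cells given siRNA against Spt6. Each RNA was labelled with Cy5 and read on its own 1-colour array, as an intensity in arbitrary units. Of 23473 probes in the table, between 21526 and 22372 had a value on any one array. Across probes, log2 intensities correlated with Pearson's r of 0.987 to 0.991 between arrays of 1 group and 0.976 to 0.981 between arrays of different groups; probes are not independent replicates. The number of arrays, 3 per group, limits the precision. The labels do not say whether the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

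The siRNA's target was examined first. The only probe named for Supt6 (listed under its older symbol Supt6h) read 33.1, 32.1 and 32.1 on the siControl arrays and 25.1, 21.8 and 28.1 on the siSpt6 arrays. The means were 32.4 ± 0.546 in siControl and 25.0 ± 3.15 in siSpt6 (intensity ± SD, n = 3 each), and all 3 siSpt6 values lay below all 3 siControl values. The log2 difference of -0.38 (SE 0.13), a level 0.767 times that of the control, did not pass the threshold across all probes (limma adjusted p = 0.0973, unadjusted p = 0.0225). After cyclic loess normalization the difference was -0.42 and passed it (limma adjusted p = 0.0491). Leaving out 1 array at a time gave limma adjusted p between 0.0728 and 0.222. Where this probe lies on the transcript is not given in the sources used here. The deposited values alone do not establish a knockdown at the threshold used.

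The largest rises in siSpt6 were in genes of differing functions, several of them dim in the control cells. Ermap, a membrane protein best known from red cell precursors, went from 7.26 ± 1.73 to 132 ± 19.7 (intensity ± SD, n = 3 each), an 18.4-fold rise. Ms4a6d, a membrane protein of the MS4A family, rose 17.2-fold from 21.4 ± 1.48 to 369 ± 45.9, and Ly6i, a member of the Ly6 family of surface proteins, rose 13.8-fold. Ephx1, an epoxide hydrolase, rose 11.0-fold. Nr4a1, an orphan nuclear receptor induced by antigen receptor signals, rose 7.90-fold from 61.5 ± 5.20 to 486 ± 30.8. The other rises among the 12 largest were Catsperd, a subunit of a sperm calcium channel (8.70-fold), Tbata (8.28-fold), Rell1 (7.69-fold), the cytokine gene Tgfb3 (7.56-fold), Fstl1 (6.97-fold), the iron regulator Hfe (6.81-fold) and Tmem86a (6.65-fold). On the log2 scale these 12 changes ran from 2.73 (Tmem86a, SE 0.47) to 4.20 (Ermap, SE 0.21). Limma adjusted p was between 0.000112 (Ms4a6d, Ly6i and Ephx1) and 0.0106 (Tmem86a). Tmem86a was the least even of them, at 75.6 ± 40.2 in siSpt6. Catsperd, Tbata, Tgfb3 and Fstl1 were very dim in the control (means 4.10, 4.70, 4.45 and 5.05), and their folds depend on a background that is not known. With a pseudocount of 2.66 their log2 changes were 2.49, 2.49, 2.35 and 2.29, against 3.12, 3.05, 2.92 and 2.80 without it. The change of Ermap, also dim, was 3.77 with the pseudocount. Each of the 12 genes was higher on all 3 siSpt6 arrays than on any siControl array, as the naming rule required.

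Among the 12 largest falls, several genes take up or interconvert amino acids. Cth, which makes cysteine from cystathionine, fell 6.76-fold from 1106 ± 118 to 164 ± 18.3 (intensity ± SD, n = 3 each). Chac1, which degrades glutathione, fell 5.34-fold from 961 ± 40.6 to 180 ± 6.82. The amino acid transporters Slc7a3 and Slc1a4 fell 4.99-fold and 4.11-fold, and the mitochondrial alanine transaminase Gpt2 fell from 37.5 ± 4.24 to 9.76 ± 3.57. Trib3, a pseudokinase induced by amino acid shortage and endoplasmic reticulum stress, fell 4.17-fold. Of lipid genes, Mfsd2a, a transporter of lysophosphatidylcholine, fell 4.97-fold and Dgat2, an enzyme of triglyceride synthesis, fell 4.17-fold. The rest were the zinc finger gene Plagl1 (5.50-fold lower), Ifrd1 (4.13-fold lower, from 2448 ± 316 to 594 ± 94.8), Sgtb (4.01-fold lower) and Arl11 (3.97-fold lower). The log2 changes of these 12 genes lay between -2.76 (Cth, SE 0.14) and -1.99 (Arl11, SE 0.20), with limma adjusted p from 0.000264 (Chac1) to 0.00409 (Gpt2). By the same rule, all 12 were lower on each siSpt6 array than on any siControl array.

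**Figure D1:**
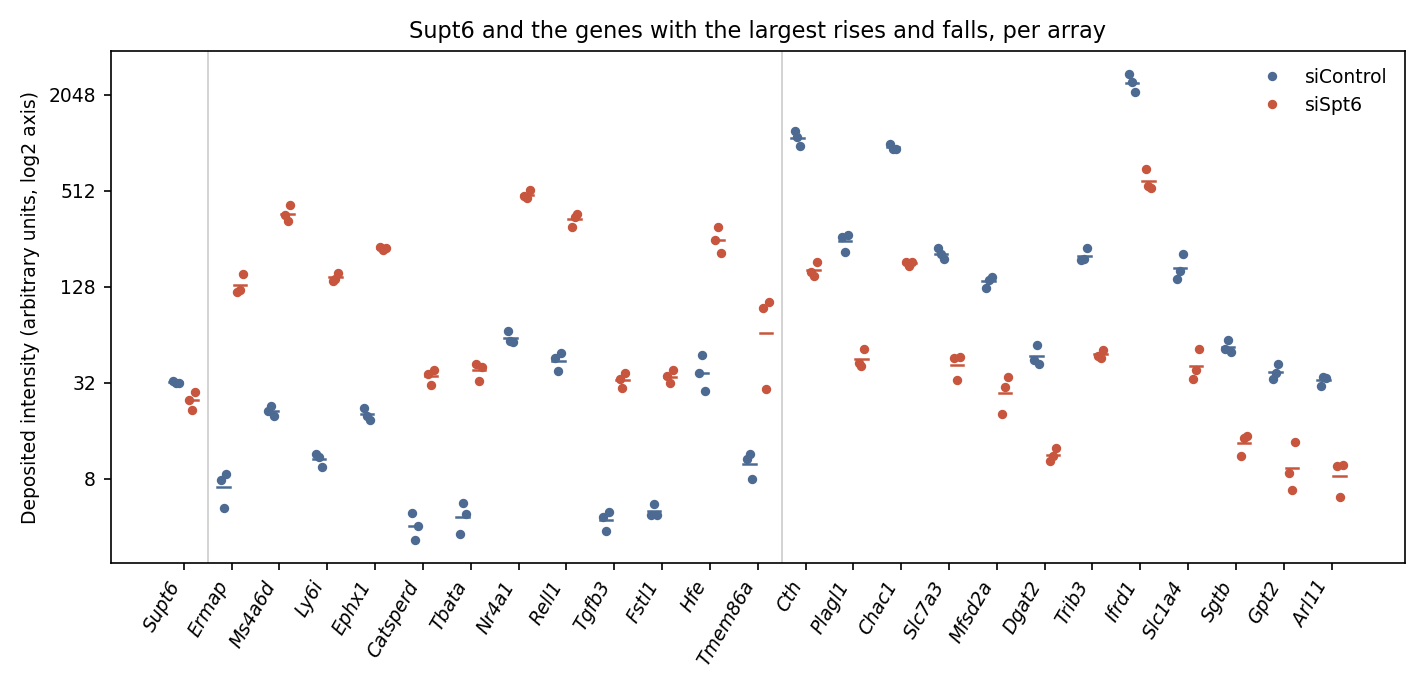
Deposited intensity (arbitrary units, log2 axis) of Supt6 and of the 12 genes with the largest rises and the 12 with the largest falls, with 1 point per array and a bar at the mean of the 3 arrays of each group. The siControl and siSpt6 points do not overlap for any gene shown, which the naming rule required of all but Supt6. The gap is small for Supt6 (32.4 against 25.0) and wide for Ermap (7.26 against 132) and Cth (1106 against 164).

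Over all genes, 3525 of 21584 tested probes (16.3%) changed, of which 1603 were higher and 1922 lower in siSpt6 (limma, Benjamini-Hochberg adjusted p under 0.05). Taking 1 probe per gene, 1126 of 15224 genes rose and 1469 fell. Changes of at least 2-fold were more often rises, with 594 probes higher and 377 lower. Of the 20336 probes measured on all 6 arrays, 37.3% had groups that did not overlap, 3443 higher and 4145 lower in siSpt6, where chance gives 10%. The balance of directions depended on the scaling: 45.5% of changed probes were higher in the deposited values, against 57.3% after quantile normalization and 53.6% after cyclic loess. Leaving out 1 array lowered the count of changed probes to between 2099 and 2522, the lowest without siControl replicate 1, and to 2230, 2308 and 2160 without siControl replicate 2, siSpt6 replicate 1 and siSpt6 replicate 2.

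Genes of cholesterol synthesis were the most uniformly lower group: 13 of 14 measured members fell and 0 rose, the same counts when adjusted over the list alone, with a median log2 change of -1.43 (camera adjusted p = 1.05e-11). Fdft1, squalene synthase, fell 2.94-fold from 1054 ± 47.3 to 359 ± 34.2, and Sc5d, a sterol desaturase, fell 2.74-fold. The member not past the test was Lss (log2 change -0.09), named after its value was seen. Of 17 glycolysis genes 12 fell and 0 rose (13 fell adjusted over the list alone), with a median of -0.91 (camera adjusted p = 1.85e-08, and adjusted p = 0.144 with an estimated correlation). Phosphofructokinase Pfkl fell 2.34-fold and hexokinase Hk2 fell 2.12-fold. Both lists stayed lower under quantile and cyclic loess normalization, and the cholesterol list kept its call with an estimated correlation (camera adjusted p = 0.0269).

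Cell cycle genes were lower as well. Of 26 genes of the G1/S transition and DNA replication, 17 fell and 0 rose (22 fell adjusted over the list alone), with a median log2 change of -0.86 (camera adjusted p = 4.41e-12, and adjusted p = 0.0269 with an estimated correlation). Tyms, thymidylate synthase, fell 2.63-fold from 923 ± 8.23 to 352 ± 11.1, and cyclin E1 (Ccne1) fell 2.40-fold from 361 ± 18.1 to 151 ± 11.0. Of 22 genes of G2/M and mitosis, 10 fell and 0 rose (15 fell adjusted over the list alone), with a median of -0.45 (camera adjusted p = 3.27e-07, and adjusted p = 0.144 with an estimated correlation). Quantile and cyclic loess normalization brought the G2/M median to -0.22 and -0.25 and the G1/S median to -0.66 and -0.69, and both lists kept their calls. Cdk1, the mitotic kinase, fell 1.79-fold, and Tpx2, a spindle assembly factor, fell 1.73-fold. None of these 4 genes lost its call when any 1 array was left out.

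Unfolded protein response genes were lower: 10 of 18 fell and 0 rose (11 fell and 1 rose adjusted over the list alone), with a median log2 change of -0.49 (camera adjusted p = 0.000158, and adjusted p = 0.144 with an estimated correlation). The median lay closer to 0, at -0.19 and -0.22, after quantile and cyclic loess normalization, where the list kept its call (camera adjusted p = 0.00159 and 0.00257). The members with the smallest adjusted p were Chac1 and Trib3, given above. Chac1, Trib3, Atf4, Ddit3 and Sesn2 are known targets or parts of the branch that the kinase PERK shares with the response to amino acid shortage. Atf4, the transcription factor at the centre of that branch, fell 2.84-fold from 3512 ± 694 to 1230 ± 221, and Herpud1, a gene of protein degradation at the endoplasmic reticulum, fell 2.81-fold; both were named after their values were seen. Ddit3 and Sesn2 were also named after their values were seen. Hspa5, the main chaperone of the endoplasmic reticulum, fell 1.39-fold, a call lost without any 1 of the 6 arrays (limma adjusted p up to 0.111) and after quantile normalization (limma adjusted p = 0.461); it too was named after its value was seen. The heat shock list did not shift (11 measured, 1 rose and 3 fell, also adjusted over the list alone, camera adjusted p = 0.626). Its median was -0.13, and its sign changed under quantile and cyclic loess normalization. Hspd1, the mitochondrial chaperonin, fell 2.09-fold. Hsp90aa1 and Hspa8 fell (log2 changes -0.63 and -0.59), but missed the threshold after quantile normalization (limma adjusted p = 0.234 and 0.299) and without siSpt6 replicate 2 or siControl replicate 2 (limma adjusted p = 0.0924 and 0.110 in turn); Hspa8 was named after its value was seen. Hspa4l rose 1.78-fold, a call lost without any 1 of 5 arrays (limma adjusted p up to 0.118).

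Cytosolic ribosomal protein genes, among the brightest probes, had 24 falls and 1 rise among 61 measured members (37 falls and 2 rises adjusted over the list alone), with a median log2 change of -0.39 (camera adjusted p = 2.42e-08, and adjusted p = 0.144 with an estimated correlation). After normalizations that remove a dependence on brightness, the median was -0.08 (quantile, camera adjusted p = 0.0752) and -0.00 (cyclic loess, camera adjusted p = 0.495). The list's call was thus lost after both. Its median log2 level was 13.6, at the bright end that both normalizations align across arrays, so they could also remove a real fall of these genes. Rpl30 and Rpl29 fell 2.32-fold and 2.03-fold and kept their calls under both normalizations, and Rpl37 rose 1.60-fold. The probes of Rpl30, Rpl29 and Rpl37 were dimmer than the list's median, with mean log2 levels of 9.19, 10.9 and 4.63. They are thus not typical of the list, and whether they report their transcripts well was not tested. Genes of oxidative phosphorylation did not shift as a group in the deposited values (74 measured, 1 rose and 4 fell, and 1 and 2 adjusted over the list alone). Their median was -0.09 (camera adjusted p = 0.436) as deposited, but 0.20 after quantile normalization (camera adjusted p = 0.0114, higher) and 0.15 after cyclic loess (camera adjusted p = 0.0125, higher). Atp5g1, Cyc1, Sdhb and Ndufs6 fell and Ndufa1 rose, by log2 changes of -0.67, -0.67, -0.50, -0.49 and 0.71. After quantile normalization Cyc1, Sdhb and Ndufs6 missed the threshold (limma adjusted p = 0.0556, 0.177 and 0.370). The rise of Ndufa1 was lost without siControl replicate 1 (limma adjusted p = 0.0535), and the falls of Sdhb and Ndufs6 were lost without any 1 of the 6 arrays (limma adjusted p up to 0.119 and 0.0902). Sdhb and Ndufs6 were named after their values were seen.

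**Figure D2:**
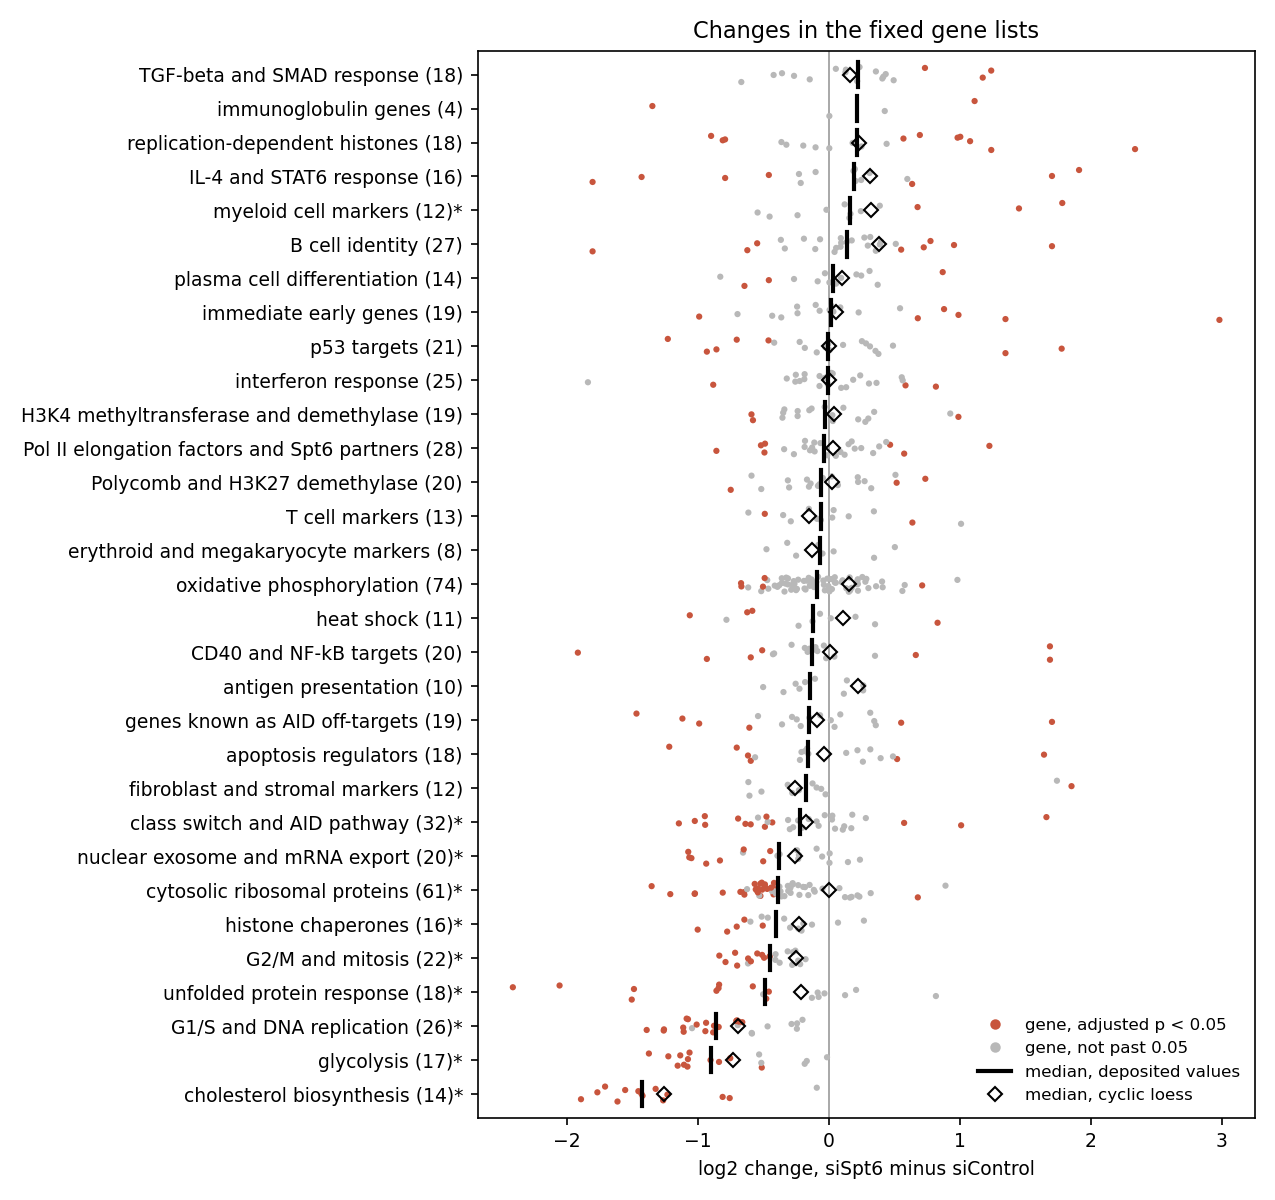
Log2 change (siSpt6 minus siControl) of each measured member of the fixed gene lists, 1 point per gene, red where the gene passed limma's adjusted p of 0.05; the bar is the list's median in the deposited values, the diamond its median after cyclic loess, the number in brackets the members measured and the asterisk a camera adjusted p under 0.05. Cholesterol synthesis (median -1.43), glycolysis (-0.91) and G1/S genes (-0.86) lie farthest to the left, and the ribosomal protein median moves from -0.39 to -0.00 after cyclic loess.

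Factors that handle nascent RNA and chromatin moved unevenly. Of 20 genes of the nuclear exosome and mRNA export, 8 fell and 0 rose (9 fell adjusted over the list alone), with a median log2 change of -0.39 (camera adjusted p = 0.000336, and adjusted p = 0.311 with an estimated correlation). The exosome subunits Exosc7 and Exosc2 fell 2.10-fold and 2.07-fold, Exosc2 from 845 ± 40.7 to 408 ± 7.71. Of 16 histone chaperone genes 5 fell and 0 rose (8 fell adjusted over the list alone), with a median of -0.41 (camera adjusted p = 0.00109, and adjusted p = 0.144 with an estimated correlation). Chaf1a and Chaf1b, subunits of the replication-coupled chaperone CAF-1, fell 2.01-fold and 1.72-fold, and Asf1b, which passes histones to it, fell 1.63-fold. Npm1 and Anp32e also fell (log2 changes -0.65 and -0.51), but missed the threshold after quantile normalization (limma adjusted p = 0.193 and 0.138) and when some arrays were left out (limma adjusted p up to 0.0612 without siSpt6 replicate 2 and 0.0791 without siControl replicate 1). Chaf1b, Npm1 and Anp32e were named after their values were seen. After quantile and cyclic loess normalization the exosome and export median was -0.24 and -0.26 and the chaperone median -0.24 and -0.23, and both lists kept their calls.

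Elongation factors and partners of Spt6 did not shift as a group: of 28 measured genes 3 rose and 4 fell (the same adjusted over the list alone), with a median log2 change of -0.04 and camera adjusted p = 0.872. Supt4a, whose product pairs with Spt5 in the elongation factor DSIF, rose 2.34-fold from 1609 ± 127 to 3759 ± 285. Nelfe, a subunit of the pausing factor NELF, fell 1.82-fold from 381 ± 17.4 to 210 ± 20.5. Cdk9, the kinase that releases paused polymerase, rose 1.49-fold and Cdc73, a subunit of the PAF complex, fell 1.43-fold; either call was lost without any 1 of 5 arrays (limma adjusted p up to 0.108 and 0.0793). Rtf1 (log2 change 0.47), Wdr61 (-0.49) and Polr2c (-0.49), named after their values were seen, passed the threshold narrowly and lost it without any 1 of the 6 arrays (limma adjusted p up to 0.134, 0.132 and 0.125). The H3K4 methylation list also showed no shift (19 measured, 1 rose, 2 fell, the same adjusted over the list alone, median -0.03, camera adjusted p = 0.872). In it, the H3K4 demethylase Kdm5b rose 1.98-fold from 18.7 ± 1.53 to 36.9 ± 0.448. Kdm5c, a related demethylase, and Men1, a subunit of MLL complexes, fell (log2 changes -0.59 and -0.58), and each lost its call without any 1 of 5 arrays (limma adjusted p up to 0.0872 and 0.0901).

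The Polycomb list held 20 measured genes, of which 2 rose and 1 fell, the same when adjusted over the list alone (median log2 change -0.06, camera adjusted p = 0.942). Cbx7 rose 1.66-fold and Jarid2 1.43-fold, calls lost without siControl replicate 2 (limma adjusted p = 0.0892 and 0.110) and without most other arrays. Rbbp7, a histone-binding subunit, fell 1.68-fold, but not past the threshold after quantile normalization (log2 change -0.42, limma adjusted p = 0.0680). Replication-dependent histone genes changed in both directions: of 18 measured, 7 rose and 3 fell (7 and 4 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 0.106). The linker histone gene H1f2 rose 5.05-fold from 130 ± 7.88 to 657 ± 70.9 and H4c1 rose 2.11-fold. The bright H2A genes H2ac15 and H2ac10 fell 1.87-fold and 1.73-fold; H2ac4 (log2 change -0.81, named after its value was seen) missed the threshold after quantile normalization (limma adjusted p = 0.107) and without siSpt6 replicate 1 (limma adjusted p = 0.0690). The histone list passed the test of a shift, as higher, without siSpt6 replicate 3 (camera adjusted p = 0.0429) and with bright probes only (13 members, median 0.57, camera adjusted p = 0.00544).

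Genes of class switching and the AID pathway were lower on balance. Of 32 measured members 3 rose and 10 fell (3 and 11 adjusted over the list alone), with a median log2 change of -0.22 (camera adjusted p = 0.0141, and adjusted p = 0.574 with an estimated correlation). Exo1, the exonuclease of mismatch repair, fell 2.22-fold from 293 ± 18.6 to 132 ± 8.92, and Ercc6l2, a factor of end joining, fell 2.04-fold. Dclre1c, which encodes the end-processing nuclease Artemis, rose 3.16-fold, to 34.3 ± 4.85 in siSpt6. Xrcc4, a partner of DNA ligase 4, rose 1.49-fold, and Hmces (log2 change 1.01, named after its value was seen) also rose; each lost its call without some 1 array (limma adjusted p up to 0.0846 without siControl replicate 1 and 0.0725 without siSpt6 replicate 3). The list itself lost its call without siControl replicate 3 (camera adjusted p = 0.0676). Igha was not analysed here.

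Genes described as off-targets of AID did not shift together: of 19 measured, 2 rose and 4 fell (2 and 5 adjusted over the list alone), with a median log2 change of -0.15 and camera adjusted p = 0.436. Gas5, a host gene of small nucleolar RNAs, fell 2.77-fold from 3168 ± 254 to 1144 ± 116, and the adaptor gene Grap fell 2.17-fold. Myc fell 1.99-fold and Ly6e (named after its value was seen) fell 1.53-fold. Cd79b, a signalling chain of the B cell receptor, rose 1.46-fold from 5787 ± 707 to 8455 ± 698. Bcl6, a repressor of germinal centre B cells, rose 3.26-fold at a dim level, from 2.28 ± 1.08 in siControl. Leaving out 1 array ended the calls of Cd79b, Bcl6, Myc and Ly6e (limma adjusted p up to 0.104 without siControl replicate 1, 0.0736 without siSpt6 replicate 3, 0.0663 without siControl replicate 2 and 0.0509 without siSpt6 replicate 1). Ly6e also missed the threshold after quantile normalization (limma adjusted p = 0.149). Of 4 immunoglobulin genes measured, 1 rose and 1 fell (2 and 1 adjusted over the list alone), too few for a test of the set. Ighm, the heavy chain gene of IgM, read 32.6 ± 2.75 in siControl and 43.7 ± 0.801 in siSpt6, a log2 difference of 0.43 that narrowly missed the threshold (limma adjusted p = 0.0511). The Ighm level lay near the array medians and far below that of Cd79b, although these cells switch from IgM. Whether the Ighm probe reports the IgM transcript well was not tested, so its value is not taken as a measure of IgM. Ighe fell 2.55-fold from 25.7 ± 3.83 to 10.2 ± 2.26. Vpreb1 rose 2.16-fold at a dim level, 4.33 ± 1.03 against 9.55 ± 3.30, a call lost without any 1 of 5 arrays (limma adjusted p up to 0.110).

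B cell identity genes showed no shift in the deposited values (27 measured, 5 rose and 3 fell, the same adjusted over the list alone, median log2 change 0.13, camera adjusted p = 0.278), and a higher level after quantile and cyclic loess normalization (camera adjusted p = 0.0221 and 0.0151). Foxo1 and Bach2, transcription factors of B cells, rose 1.94-fold and 1.71-fold, and the kinase gene Blk rose 1.65-fold. Fcer2a, the low-affinity IgE receptor CD23, fell by 1.81 on the log2 scale, from 115 ± 5.60 to 33.3 ± 6.82. The inhibitory receptor gene Cd22 fell 1.54-fold and the kinase gene Syk fell 1.46-fold. Blk and Syk were named after their values were seen, and Blk, Cd22 and Syk each lost their call without some 1 array (limma adjusted p up to 0.107, 0.0830 and 0.0964). Plasma cell genes did not shift (14 measured, 1 rose and 2 fell, 1 and 3 adjusted over the list alone, median 0.03, camera adjusted p = 0.872). Ly6c1 rose 1.83-fold, and Cd28 and Xbp1 fell 1.57-fold and 1.38-fold, the falls missing the threshold after quantile normalization (limma adjusted p = 0.0675 and 0.357); Xbp1 also missed it without any 1 of the 6 arrays (limma adjusted p up to 0.132). None of 10 antigen presentation genes passed the test, over all probes or adjusted over the list alone (median -0.15, camera adjusted p = 0.827).

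Lists of targets and pathway members were examined for the 3 CIT signals. Genes of the CD40 and IL-4 lists changed in both directions, while the called changes in the TGF-beta list were all rises. None of the 3 lists shifted as a whole by camera. Of 20 CD40 and NF-kB target genes 3 rose and 4 fell (3 and 6 adjusted over the list alone, median log2 change -0.13, camera adjusted p = 0.441). The chemokine gene Ccl22 fell 3.78-fold from 7150 ± 575 to 1893 ± 190 and the death receptor gene Fas fell 1.91-fold. The chemokine genes Ccl3 and Ccl4 both rose 3.22-fold, Ccl3 from 108 ± 7.81 to 348 ± 9.40. Birc3, an inhibitor of apoptosis, also fell (log2 change -0.60), as did Tnfaip3 (-0.51), an inhibitor of NF-kB signalling, while Rel (0.66), a subunit of NF-kB, rose. Rel and Tnfaip3 were named after their values were seen, and each lost its call without siControl replicate 1 (limma adjusted p = 0.0645 and 0.103), Tnfaip3 also after quantile normalization (limma adjusted p = 0.0663). Of 16 genes of the IL-4 and STAT6 response 3 rose and 4 fell (4 and 4 adjusted over the list alone, median 0.19, camera adjusted p = 0.730). Gfi1, a transcriptional repressor, rose 3.76-fold from 20.8 ± 0.773 to 78.5 ± 7.24, and Batf3, a transcription factor of the AP-1 family, fell 2.70-fold from 191 ± 5.14 to 70.7 ± 3.27; Fcer2a, Bcl6 and Xbp1, given above, are also in this list. Socs1, an inhibitor of cytokine signalling, rose and Batf fell (log2 changes 0.63 and -0.79), both named after their values were seen. Leaving out 1 array ended the calls of Socs1, Bcl6 and Xbp1 (limma adjusted p up to 0.0806, 0.0736 and 0.132). Of 18 TGF-beta and SMAD response genes 3 rose and 0 fell (6 and 2 adjusted over the list alone, median 0.22, camera adjusted p = 0.104). These were Skil and Ski, which repress SMAD proteins, with log2 changes of 1.24 and 0.73, and Smad3, which was dim at 2.30 ± 0.514 and 5.17 ± 1.05. Ski, named after its value was seen, lost its call without siControl replicate 2 (limma adjusted p = 0.0546).

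The p53 and apoptosis lists did not shift by camera. Of 21 p53 targets 2 rose and 5 fell (4 and 6 adjusted over the list alone, median log2 change -0.01, camera adjusted p = 0.872). Trp53inp1, a p53-induced regulator of death and autophagy, rose 3.43-fold from 99.5 ± 2.40 to 342 ± 32.5 and Btg2, an antiproliferative gene, rose 2.54-fold. Phlda3, Fas, Sesn2, Bbc3 and Sesn1 fell, by log2 changes of -1.23, -0.93, -0.86, -0.71 and -0.46. Of 18 apoptosis regulators 2 rose and 4 fell (3 and 5 adjusted over the list alone, median -0.16, camera adjusted p = 0.730). With the mean of a gene's probes the median was -0.01 and the camera direction turned from lower to higher (camera adjusted p = 0.946). Cflar, an inhibitor of caspase 8, fell 2.33-fold from 122 ± 6.54 to 52.4 ± 1.17, and Birc3 and Bcl2 fell 1.51-fold and 1.54-fold. Bmf, a death-promoting gene of the BCL2 family, rose 3.12-fold at a dim level (2.69 ± 0.938 against 8.07 ± 1.40), and Casp8 rose 1.43-fold. Of these, Sesn2, Bbc3, Sesn1 and Bcl2 were named after their values were seen. The calls of Sesn1, Bbc3 and Casp8 were lost when 1 array was left out (limma adjusted p up to 0.118 without siControl replicate 1, and 0.0804 and 0.0770 without siSpt6 replicate 2), and Sesn1 and Bcl2 missed the threshold after quantile normalization (limma adjusted p = 0.174 and 0.0645).

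Of 19 immediate early genes 5 rose and 1 fell (5 and 2 adjusted over the list alone, median log2 change 0.02, camera adjusted p = 0.436). The rises were Nr4a1 and Btg2, given above, and Fos, Zfp36 and Egr2, named after their values were seen, with log2 changes of 0.99, 0.88 and 0.68; the fall was Myc, also above, which lost its call without siControl replicate 2 (limma adjusted p = 0.0663). Of 25 interferon response genes 2 rose and 1 fell (the same adjusted over the list alone, median -0.01, camera adjusted p = 0.730). Irf9, a transcription factor of the interferon pathway, rose 1.76-fold, and Isg20 fell 1.85-fold. Mx2 rose at a dim level (log2 change 0.58), a call lost without siControl replicate 2 (limma adjusted p = 0.0644). Where no list shift was called, the sign of a list's centre depended on the measure: median and camera direction differed for the elongation, Polycomb, plasma cell and interferon lists, and median and mean differed for the elongation, H3K4, plasma cell, p53, T cell and fibroblast lists. The medians of the elongation, H3K4, Polycomb, antigen presentation, CD40 and NF-kB lists also changed sign under quantile and cyclic loess normalization, and those of the interferon and p53 lists under quantile normalization.

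Markers of other cell types were examined because a culture could hold other cells. Myeloid markers were higher: 3 of 12 measured rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00721 on the 7 members with a value on all 6 arrays, and adjusted p = 0.144 with an estimated correlation). Cd300a, an inhibitory receptor, rose 3.44-fold, to 206 ± 9.59 in siSpt6, and Tyrobp, an adaptor of activating receptors, rose 2.73-fold from 261 ± 29.6 to 715 ± 111. Csf3r, named after its value was seen, rose 1.60-fold at a dim level, a call lost after quantile normalization (limma adjusted p = 0.0738) and without any 1 of 5 arrays (limma adjusted p up to 0.130). Csf1r, Cd68 and S100a8 did not pass the test (log2 changes 0.12, 0.24 and -0.02); they too were named after their values were seen. Of 13 T cell markers 1 rose and 1 fell (2 and 1 adjusted over the list alone, median -0.06, camera adjusted p = 0.730). They were Cd5 (1.55-fold higher), also a B cell surface protein, and Tcf7 (1.41-fold lower), whose calls were lost without any 1 of 4 and of 5 arrays (limma adjusted p up to 0.0847 and 0.109). None of 8 erythroid and megakaryocyte markers passed the test, over all probes or adjusted over the list alone (median -0.07, camera adjusted p = 0.827). Of 12 fibroblast and stromal markers 1 rose and 0 fell, also adjusted over the list alone (median -0.18, camera adjusted p = 0.730); this was Acta2, dim at 4.81 ± 1.53 and 16.8 ± 2.72, and 3.61-fold higher.

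Bright probes were lower in siSpt6 than in siControl although the arrays' medians were alike. The mean intensity over measured probes was 403 ± 5.94 in siControl and 333 ± 5.57 in siSpt6, and the 99th percentile was 8362 ± 158 and 6569 ± 92.7 (SD, n = 3 each). In the brightest 10% of probes the median log2 change was -0.26, with 115 probes higher and 585 lower. In the 10% of probes next to the dimmest 10% it was 0.12, with 117 higher and 39 lower. Some probes had values in 1 group only: 55 were measured on all 3 siSpt6 arrays and on no siControl array, and 12 the other way round. No test applies to these counts, and the other 9 ways to split the 6 arrays into groups of 3 gave between 33 and 81 such probes in all, against 67 for the real groups.

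**Figure D3:**
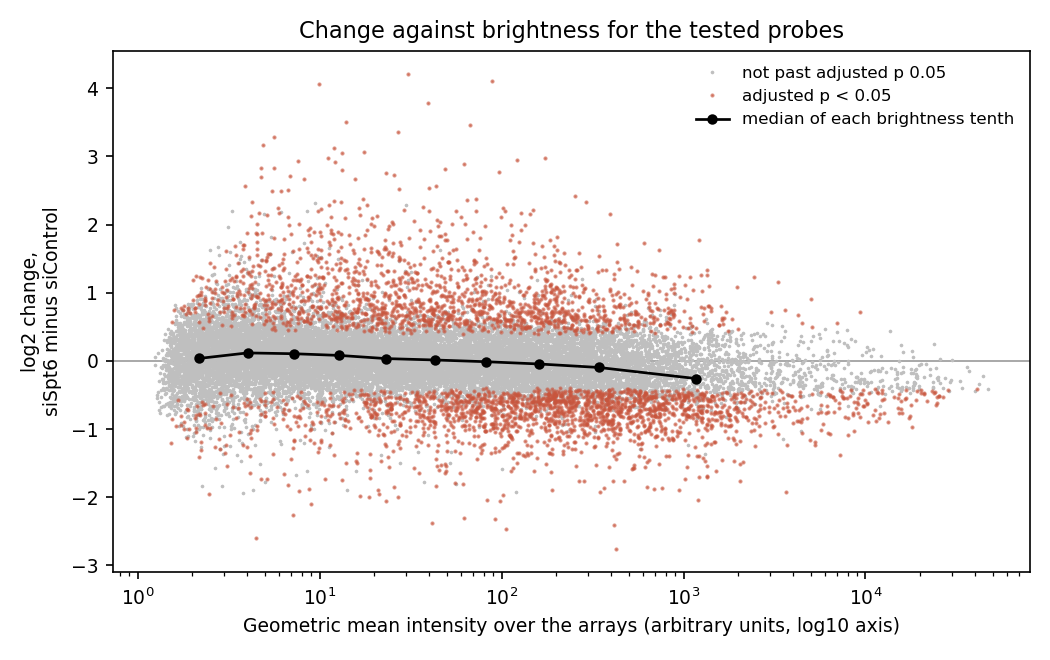
Log2 change (siSpt6 minus siControl) of each tested probe against its geometric mean intensity over the arrays (arbitrary units, log10 axis), red where limma's adjusted p was under 0.05, with the medians of 10 brightness classes of like size joined by the black line. The line falls from 0.12 in the class next to the dimmest to -0.26 in the brightest.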

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

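Cyclic loess for the gene lists, and both normalizations for the trend with brightness, were chosen after seeing the data; the other alternatives were fixed before. The deposited values gave 3525 changed probes, and other scalings, filters and variance models gave between 3232 (quantile normalization) and 4568 (eBayes with trend and robust options). The split of directions moved with the scaling and the filter: 1853 probes were higher and 1379 lower after quantile normalization, and 1459 higher and 2515 lower among the brighter probes alone, against 1603 and 1922. Stricter thresholds gave 971 probes (594 higher, 377 lower) at 2-fold or more and 1354 (649 higher, 705 lower) at an adjusted p of 0.01, by construction fewer. Leaving out 1 array gave 2099 to 2522 changed probes, 1047 to 1124 higher and 1052 to 1421 lower, with fewer arrays in each fit. Supt6 passed the threshold only after cyclic loess (log2 change -0.42, limma adjusted p = 0.0491), among alternatives that gave it limma adjusted p from there up to 0.222; the cause was not tested. An estimated correlation left 2 of 10 gene list calls. That setting changes both the correlation and the degrees of freedom, which were not tested apart. For the histone chaperone and myeloid lists the estimate was -0.032 and -0.018, below the fixed 0.01. Their unadjusted camera p still rose, from 0.00029 to 0.0177 and from 0.00216 to 0.0342. This argues against a higher correlation as the reason for these lost calls. The oxidative phosphorylation list turned from no call (median -0.09) to higher with quantile normalization (camera adjusted p = 0.0114) and cyclic loess (camera adjusted p = 0.0125). Fry, a test with another question, also passed the histone, TGF-beta, apoptosis and immediate early lists (fry adjusted p = 0.00375, 0.0369, 0.0317 and 0.0242). Requiring a value on at least 2 of 3 arrays of one group and none of the other gave 199 probes only in siSpt6 and 82 only in siControl. Of the 3525 calls, between 56.7% and 66.4% were kept when 1 array was left out, 80.3% with quantile normalization and 81.1% with cyclic loess. Of 100 genes named by the rule and with a call, 0 changed direction under any alternative run. The call was lost by 20 when some 1 array was left out, by 6 with quantile normalization and by 4 with cyclic loess. The rule picked these genes for clear changes in the same arrays, so they do not measure how stable all calls are.

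The same replicate numbers stand in both groups. Deviations from the group means correlated between same-numbered arrays with r of 0.351, 0.0759 and 0.262 across probes, which was too low for 1 pair to take the numbers as pairing the samples, although each siControl array correlated best with its own number, a hint from the data and not from the design. With the replicate number as a block, 3610 probes changed (1633 higher, 1977 lower), 3069 of them shared with the fit without it, and 4 of the genes named by the rule lost their call (Xrcc4, Cd79b, Hspa4l and Tcf7). Of genes named after their values were seen, Csf3r, Rtf1, Tnfaip3, Bbc3, Sdhb and Rel lost it (limma adjusted p = 0.0978, 0.0674, 0.0582, 0.0579, 0.0573 and 0.0503). In the simulation, where few probes changed, 40.3% of probes with a 2-fold change were recovered over all brightness levels. That rate does not carry over to the real comparison, and recovery among dim probes alone was not examined.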

Other observations

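The 5 gene lists of the next paragraphs were chosen only after the results they bear on were seen. So were the test of the myeloid markers and that of the ribosomal proteins after cyclic loess. The test of the lower lists with cyclic loess was chosen after their shifts were seen but before its own result. The tests of gene length and of chromosomes were set before their results were seen. P-values of the 5 lists were adjusted over those 5 alone, not together with the fixed lists. The same unadjusted p can thus give a smaller adjusted p here. Calls of the 5 lists, with an estimated correlation too, are therefore not on one footing with calls of the fixed lists. Genes that charge tRNAs with amino acids were lower in siSpt6: of 17 aminoacyl-tRNA synthetase genes 13 fell and 1 rose, with a median log2 change of -0.83 (camera adjusted p = 1.82e-07, and adjusted p = 0.0189 with an estimated correlation). Nars fell 2.90-fold and Cars 2.64-fold. The rise was Qars (log2 change 0.49), a call lost without any 1 of the 6 arrays (limma adjusted p up to 0.124). Of 25 genes of amino acid synthesis and transport 21 fell and 0 rose, with a median of -1.13 (camera adjusted p = 2.59e-14, and adjusted p = 0.0189 with an estimated correlation). Without the 4 members that the report had already named, 17 of 21 fell (camera adjusted p = 4.67e-11). Bcat1 and Psat1, which make or convert branched-chain amino acids and serine, fell 3.41-fold each, from 873 to 256 and from 3775 to 1104 in mean intensity. The asparagine synthetase gene Asns, known like Chac1 and Trib3 as a target of Atf4, did not pass the test (log2 change 0.12), on a dim probe reading 5.41 in siControl and 5.79 in siSpt6.

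Of 37 ribosome biogenesis genes 25 fell and 0 rose, with a median log2 change of -0.68 (camera adjusted p = 2.27e-11, and adjusted p = 0.00675 with an estimated correlation). Dkc1, of the enzyme complex that modifies ribosomal RNA, fell 2.30-fold and Ppan 2.09-fold. Lysosomal genes went the other way, with 13 of 26 higher and 0 lower, a median of 0.55 (camera adjusted p = 1.73e-06, and adjusted p = 0.0475 with an estimated correlation). Naglu rose 2.62-fold, Lamp1 2.15-fold from 944 to 2031, and Tpp1 1.97-fold. Lysosomal genes such as Ctss and Lgmn (1.75-fold and 1.98-fold higher) are also abundant in myeloid cells, so the rise of the myeloid markers Cd300a and Tyrobp bears on this list, and whether other cells raised it is left open. All 4 of these lists kept direction and call after quantile and cyclic loess normalization. Of 25 genes that FOXO factors are known to induce 6 rose and 1 fell, with a median of 0.13 (camera adjusted p = 0.00394, and adjusted p = 0.0558 with an estimated correlation). Its call hung on single members: it was lost without the 3 members named by the rule (camera adjusted p = 0.0605) and kept when Sesn1, the fall, which the report had also named, was left out as well (camera adjusted p = 0.0262), so this list is left open. S1pr1, the receptor that draws lymphocytes out of tissue, rose 4.51-fold in it.

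The lower gene lists could come from the way the arrays were scaled, since bright probes were lower in siSpt6. Cyclic loess removes any smooth dependence on brightness, and 8 of the 9 lists that were lower stayed lower after it, which argues against that dependence as the whole cause for those 8. A batch that parts the groups stays open: 3 of 4 protocol fields of the labels are worded differently in the 2 groups, no label gives a batch or date, and batch and treatment cannot be told apart. With 10 ways to split 6 arrays into groups of 3, no share under 0.05 can be reached; only 1 split, the real one, gave as many changed probes (3525), and the highest of the others gave 0.

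The exception was the ribosomal proteins. Their median moved from -0.39 in the deposited values to -0.00 after cyclic loess (camera adjusted p = 0.495). That move cannot part a fall of these genes from a difference between arrays, since they lie at the bright end that cyclic loess aligns. They lay only -0.09 from the probes nearest in brightness (SD 0.357 over members), so their level was near that of other bright probes. For the brightest members those neighbours were mostly dimmer, because few probes lie above them. Oxidative phosphorylation genes lay at 0.19 from their own neighbours, 0.286 higher than the ribosomal proteins. Part of that gap could come from the dimmer neighbours of the ribosomal proteins, so its size is not exact. After cyclic loess the oxidative phosphorylation list was called higher and the ribosomal list was not called, as given above. Whether bright probes were lower because of the scaling, of saturation or of the cells stays open, since no spike-in or total RNA measure was analysed here.

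Myeloid cells among the siSpt6 cultures are a possible explanation for the rise of Cd300a and Tyrobp, and the values leave it open. Over all 12 measured myeloid markers the median log2 change was 0.159, against 0.68 for the smallest called rise. The SE of their mean, 0.203, is taken over markers, which are not independent replicates. Of the 12 markers 7 were dimmer than the median probe. S100a8, Csf1r and Cd68 read 36.4, 60.5 and 182 in siControl and 35.8, 65.3 and 217 in siSpt6, none past the test, at baselines that could hide a small share of other cells. A change of Cd300a and Tyrobp within the B cells also stays open, and so does the source of the lysosomal rise.

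Long genes could fall more than short ones if loss of an elongation factor hampered long transcripts. Across 14887 genes, which are not independent replicates, the log2 change did not follow gene length (Spearman's rho 0.00572), and within classes of like brightness rho lay between -0.0237 and 0.0613. A difference in chromosome number between the cultures would move whole chromosomes. The most deviating, chromosome 14, had a median log2 change only 0.0437 above that of all other genes.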
